A study of Mus musculus with 19 samples.

How the data were processed

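Ribosome profiling and RNA-seq were made from acute hippocampal slices of male mice aged 28 to 35 days, Fmr1 KO and WT littermates. Per the labels, 8 to 10 slices of 400 µm from 6 to 8 mice were pooled for each biological replicate, rested at 30 °C for 3 to 4 h and treated with cycloheximide at 100 µg/ml, and cytoplasmic RNA and ribosome footprints (RPF) came from the same lysate. The protocol describes removing CA3 to enrich CA1, while the source name gives hippocampal-cortical slices, so the tissue is called hippocampal slices here. The labels list 19 samples and the tables hold 14 libraries: 3 KO and 4 WT for RNA, and 3 KO and 4 WT for RPF. The other 5 samples are not analysed here.

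Per the labels, reads were trimmed with cutadapt 1.7.1 and Trimmomatic 0.32, aligned to mm10 with Bowtie2 2.1.0 and TopHat2 2.0.9, handled with SAMtools 0.0.19 and bedtools, and quantified with RSEM 1.2.11. The values deposited by the authors are estimated counts and TPM (normalised transcript abundance) for 14459 genes. Of the count values 100% are not whole numbers and 0% are 0. The ratio of count to TPM is a gene term times a library term to within 9.66e-15 (natural log). The lowest mean TPM of a gene is 1.03 in RNA and 1.01 in RPF, and the lowest single value in each library is 0.88 to 1 TPM. TPM totals are 1008322 to 1014087, above the total that TPM is scaled to. The values thus have a floor near 1 TPM that removal of low genes alone would not give. The labels do not state its source, and fold changes of genes near the floor are uncertain. Within groups, a single direction of the libraries, replicates 1 and 2 against 3 and 4 (cosine 0.998 in both assays), holds 1.91% of the variance in RNA and 3.64% in RPF, against 17.6% to 33.4% for each other direction. This pattern is what an adjustment for replicate sets with genotype kept would leave, and the labels do not mention one. The variance over the mean of genes with mean counts of 20 to 50 was 0.380 (KO) and 0.406 (WT) in RNA and 0.158 and 0.174 in RPF, below the Poisson value of 1. The p-values take no account of such an adjustment and may be too small.

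Library totals were 4.97 to 9.96 M estimated counts in RNA and 15.57 to 22.71 M in RPF, with median gene counts of 114 to 229 and 329 to 482. Because low counts vary less than counting noise would give, counting intervals are not given and spread is taken from replicates. Gene symbols were matched to GRCm38 annotation (13729 directly, 691 through a synonym, 39 not matched).

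Estimated counts were rounded and tested within each assay with edgeR 4.0.16 (filterByExpr with minimum count 10, TMM scaling, robust quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. SE is the absolute log2 fold change over the square root of F. Translational efficiency (TE) was tested as the interaction of assay and genotype over all 14 libraries. That fit had no term for the lysate shared by RNA and RPF, so its p-values treat the 14 libraries as independent. Every adjusted p of a gene is from edgeR unless another tool is named. Of 42 gene lists written from general knowledge, 40 had at least 5 measured genes and were tested with camera in limma 3.58.1 (preset correlation 0.01, prior count 2), with the correlation estimated from the data as an alternative. List members were counted as higher or lower after adjustment over all genes and over the list alone. For WT the ratio of RPF to RNA counts, each scaled to the library total (CPM), was ranked by list.

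The comparisons, lists, alternatives and the rule for naming genes were written before the data were examined. The rule names Fmr1, the 10 largest increases and decreases with an adjusted p under 0.05, a mean of at least 2 CPM and all KO libraries on one side of the WT mean, and up to 4 members with the smallest p of each list described. A gene that the rule names is not reported here. The edgeR test is the one written beforehand, but limma had been named as the test after the units were examined, and the return to edgeR was made with the counts of both in view. Ttr, Hbb-bs and the lists drawn in the figure were chosen after their values were seen.

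The test was tried on simulated data with 200 changed genes. Counts were drawn from a negative binomial distribution (dispersion 0.004), whose variance exceeds the Poisson value. Low counts of the deposited data vary less than that, so the rates below may not carry over to them. At log2 changes of 0.25, 0.5, 1 and 2 it recovered 24%, 72%, 94% and 100% of genes in RPF, 10.2%, 54.2%, 83.0% and 100% in RNA, and 6.12%, 51.1%, 81.3% and 100% in TE. False calls numbered 5 of 149 in RPF, 12 of 128 in RNA and 4 of 116 in TE. With a direction of the libraries removed from the simulated data they numbered 9 of 157, 3 of 122 and 20 of 123.

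Alternatives were DESeq2 1.42.0, limma on log2(TPM + 1), voom with quality weights, other scalings and filters, a fit over all libraries together, a replicate block, a length trend removed per library (loess span 0.5), fry for lists, and each library left out in turn. Gene length here is the ratio of count to TPM, averaged over the libraries, and not a length on the genome. The apparent removed direction as a covariate was added after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.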

Results

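Acute hippocampal slices from young male mice lacking Fmr1 (KO) were compared with slices from wild-type (WT) littermates by ribosome profiling, which sequences the mRNA fragments protected by ribosomes (footprints, RPF), and by RNA-seq of cytoplasmic RNA from the same lysates. Fmr1 encodes FMRP, an RNA-binding protein that is lost in fragile X syndrome and binds many neuronal mRNAs. The comparisons ask which mRNAs carry more or fewer footprints without FMRP, relative to other mRNAs, and how far the RNA level changes with them. Scaling within each assay puts the typical gene near 0 (median log2 fold change -0.0003 in RPF and -0.005 in RNA). A rise or fall shared by all genes therefore cannot be seen in footprints, RNA or TE. Each assay is represented by 3 KO and 4 WT libraries, and the n of every value is 3 for KO and 4 for WT.

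Fmr1 (GRCm38 chromosome X, 68678536 to 68717963) had the strongest decrease in KO footprints. Its footprints fell from 44.4 ± 1.53 TPM (mean ± SD, n = 4) in WT to 4.81 ± 0.222 TPM (n = 3) in KO, a log2 fold change of -3.21 ± 0.06 (SE, adjusted p = 9.08e-12, edgeR). Its RNA fell from 17.3 ± 1.46 TPM to 4.42 ± 0.771 TPM, a log2 fold change of -2.01 ± 0.11 (adjusted p = 9.91e-08). In both assays every KO library lay below every WT library. KO RNA spanned 3.90 to 5.31 TPM against 16.0 to 19.3 TPM, and KO footprints 4.59 to 5.03 TPM against 42.7 to 46.3 TPM. The footprints fell further than the RNA, by -1.20 ± 0.15 on the log2 scale in the test of the difference between the assays (adjusted p = 0.00107). Gene-level values do not show which part of the transcript the remaining KO reads come from.

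**Figure D1:**
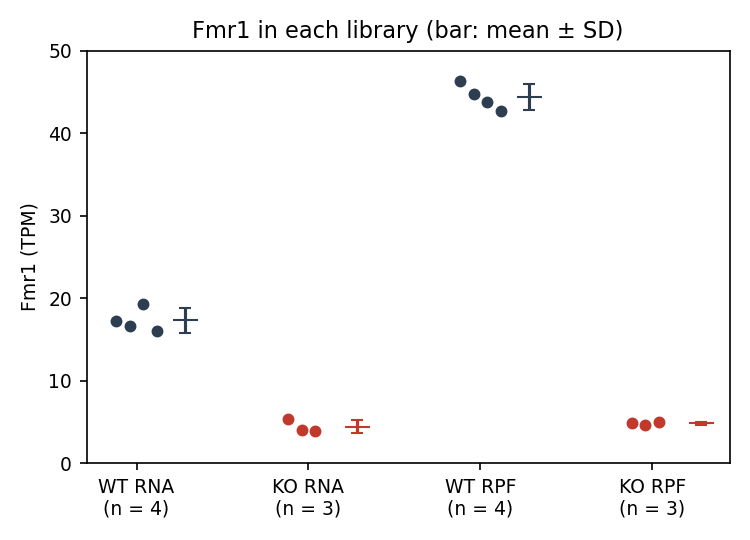
Fmr1 TPM (vertical axis) for each WT and KO library of RNA-seq and ribosome profiling, with the group mean and SD beside the points. Every KO library lies below every WT library of its assay, and KO footprints sit at 4.81 TPM against 44.4 TPM in WT.

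Beyond Fmr1, Serpina3n, a secreted protease inhibitor raised in reactive astrocytes, fell from 76.1 ± 3.24 to 41.1 ± 5.16 TPM, a log2 fold change of -0.90 ± 0.07 (adjusted p = 9.92e-05). Prelp, a matrix proteoglycan, fell by 0.84 ± 0.05 on the log2 scale (adjusted p = 1.40e-05), and Gabra2, the alpha2 subunit of the GABA-A receptor (chromosome 5, 70958392 to 71095849), fell from 459.7 ± 8.53 to 299 ± 10.5 TPM, a log2 fold change of -0.63 ± 0.04 (adjusted p = 1.40e-05). Klk8, a secreted neuronal protease, fell by 0.61, and the muscarinic receptor gene Chrm5 and the netrin gene Ntn5 each fell by 0.64. The chemokine gene Ccl12 fell by 0.74. The alpha-globin gene Hba-a2, a red blood cell transcript with a near-identical paralog that shares its reads, had a log2 fold change of -1.60 ± 0.12.

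Lmna, which encodes the lamins A and C of the nuclear envelope, rose from 24.3 ± 0.995 to 34.9 ± 3.42 TPM, a log2 fold change of 0.52 ± 0.06 (adjusted p = 5.78e-04). Hes5, a transcriptional repressor downstream of Notch, rose by 0.47 ± 0.08. Arpc1b, a subunit of the actin-branching Arp2/3 complex, rose by 0.45 ± 0.08, and the nuclear receptor corepressor gene Lcor by 0.45 ± 0.06. Hist1h2bf, Chchd2 and Ftl1 also rose, with log2 fold changes of 0.60, 0.50 and 0.45, but belong to families or have pseudogenes that share reads, so their values are uncertain. The replication licensing gene Cdt1 rose by 0.43 ± 0.07, and Prkcd, a protein kinase C gene abundant in thalamic neurons, by 0.46 ± 0.15.

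In all, edgeR called 1167 genes higher and 1501 lower in KO footprints of 14438 tested, or 18.5% of genes. The changes were small: the median absolute log2 fold change of the called genes was 0.20, and only 4 of the higher and 15 of the lower genes changed by at least 1.5-fold. The count of higher genes dropped to 754 without KO footprint library 3 and to 717 without WT footprint library 4. With the replicate number as a block 421 were higher and 872 lower. Single libraries also decided a few named genes. Chchd2 missed the threshold without KO library 1, Cdt1 without KO library 3, Ly6a (an endothelial surface protein, log2 fold change -0.59 ± 0.14) without WT library 3, and Sec14l3 (a lipid-binding protein gene, -0.57 ± 0.07) without KO library 2, with adjusted p from 0.0506 to 0.0875. Prkcd missed it without KO library 1, 2 or 3 and without WT library 1 or 3, with an adjusted p of up to 0.174 over all alternatives. Sec14l3 footprints lay near the floor of the values, at 1.61 TPM in KO and 2.37 TPM in WT, so the size of its change is uncertain. Footprint means were also low for Cdt1 (2.06 TPM in WT), Chrm5 (2.62 TPM in KO), Hba-a2 (2.74 TPM in KO) and Lcor (2.97 TPM in WT). The floor may affect the size of their changes too.

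Of 40 gene lists fixed before the data were examined, 25 shifted in KO footprints relative to all other genes, 18 down and 7 up (camera with a preset correlation of 0.01). With a correlation estimated from the data none of the 25 passed. The lists that shifted down include many genes of neuronal membrane proteins. Of 72 protocadherins, adhesion molecules of neurons, 31 fell, 0 rose and 41 did not pass (median log2 fold change -0.16, adjusted p = 3.36e-11, or 0.264 with an estimated correlation), with Pcdh20 at -0.35 ± 0.04 and Pcdh19 at -0.23 ± 0.04. Adjusted over the list alone, 43 fell. Clustered members such as Pcdhgc5 (-0.28 ± 0.04) share exons and reads, so their single values are uncertain. Of 60 postsynaptic density and glutamate receptor genes, 27 fell and 4 rose (29 and 4 adjusted over the list alone), with a median of -0.13 (adjusted p = 2.28e-08, or 0.306 with an estimated correlation), and 17 of the 60 also belong to the FMRP-bound list. Among them were the NMDA receptor gene Grin2a (-0.34 ± 0.03), the kainate receptor gene Grik4 (-0.38 ± 0.04), the metabotropic receptor gene Grm5 (-0.27 ± 0.03) and the AMPA receptor gene Gria1 (-0.25 ± 0.03). Grik4 is also counted in the CA3 marker list below. Of 13 GABA-A receptor subunits, 9 fell and 0 rose (9 adjusted over the list alone; median -0.16, adjusted p = 9.72e-06, or 0.295 with an estimated correlation), including Gabrg1 (-0.27 ± 0.04) and Gabra3 (-0.27 ± 0.04). Of 29 voltage-gated sodium and calcium channel genes, 16 fell and 1 rose (18 and 1 adjusted over the list alone; median -0.14, adjusted p = 1.28e-06, or 0.306 with an estimated correlation), among them Cacna1i (-0.37 ± 0.04) and Scn1a (-0.23 ± 0.04). Potassium channels had a median of -0.07, with 14 of 78 lower and 2 higher (15 and 2 adjusted over the list alone; adjusted p = 0.00261, or 0.485 with an estimated correlation).

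Neuropeptide and growth factor genes, whose products are secreted, also fell. Of 28 members 14 fell and 2 rose (17 and 2 adjusted over the list alone; median -0.17, adjusted p = 7.15e-07, or 0.264 with an estimated correlation). Penk, which encodes proenkephalin, fell by 0.50 ± 0.04 on the log2 scale, Vgf by 0.37 ± 0.04 and Chga by 0.29 ± 0.05. Penk is also counted in the striatal marker list below. The 143 FMRP-bound mRNAs, a partial list written from general knowledge, had a median of -0.08 (adjusted p = 2.75e-05, or 0.485 with an estimated correlation). In this list 48 fell, 11 rose and 84 did not pass (52 and 12 adjusted over the list alone), with Plxna2, a semaphorin receptor gene, at -0.29 ± 0.03. These mRNAs are long: their median length, taken from the ratio of count to TPM, was 4.17 times the median of all genes. After each library's length trend was removed the median of the list was -0.01 (adjusted p = 0.481).

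Several lists of soluble cytosolic and nuclear machinery moved the other way. Of 89 splicing factors 33 rose and 1 fell (41 and 1 adjusted over the list alone; median 0.09, adjusted p = 7.58e-11, or 0.264 with an estimated correlation), among them Ewsr1 (0.38 ± 0.04), Hnrnpf (0.30 ± 0.05) and Celf5 (0.26 ± 0.04). Of 38 proteasome subunits 15 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.11, adjusted p = 5.02e-08, or 0.306 with an estimated correlation), with Psmb4 at 0.18 ± 0.03. Of 66 translation factors 20 rose and 0 fell (24 and 0 adjusted over the list alone; median 0.09, adjusted p = 3.94e-06, or 0.264 with an estimated correlation), with the initiation factor gene Eif4b at 0.24 ± 0.04 and the poly(A)-binding protein gene Pabpc1 at 0.23 ± 0.04. Of 32 tubulin and microtubule-associated genes 14 rose and 4 fell (17 and 5 adjusted over the list alone; median 0.12, adjusted p = 2.40e-04, or 0.306 with an estimated correlation). Tubb2a (0.24 ± 0.04) and Tuba1a (0.29 ± 0.05), which have close paralogs, were among those that rose, and Map2 fell (-0.26 ± 0.05). Aminoacyl-tRNA synthetases (median 0.08, 4 rose and 1 fell of 23, the same counts adjusted over the list alone, adjusted p = 0.00701) and mitochondrial ribosomal proteins (median 0.04, 7 rose of 77, 5 adjusted over the list alone, adjusted p = 0.0229) shifted up less. Their adjusted p were 0.485 and 0.518 with an estimated correlation. The call for the mitochondrial ribosomal proteins was lost without KO footprint library 2 (adjusted p = 0.130), KO library 3 (0.0662) or WT library 2 (0.0577). Cytosolic ribosomal proteins had a median of 0.02 (adjusted p = 0.163), mTORC1 pathway genes 0.06 (0.0544), autism-linked genes -0.03 (0.107), chromatin modifiers 0.02 (0.390), presynaptic genes 0.00 (0.989) and immediate-early genes -0.03 (0.900), and these lists did not pass. Stress response genes did not pass either, with median, mean and test differing in sign (0.02, -0.01, up, adjusted p = 0.989). Some of these outcomes depended on gene length. With each library's length trend removed, chromatin modifiers (median 0.05, camera adjusted p = 0.00207) and mTORC1 genes (0.06, 0.0406) passed upward. So did kinesins with dyneins (0.05, 0.0147) and respiratory chain genes (0.03, 0.0263), which had not passed before (0.217 and 0.0731). CA1 markers passed downward (-0.12, 0.0329, against 0.0731 before).

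Markers of cell types and regions moved as well. Microglia markers fell: 16 of 22 were lower and 0 higher (19 and 0 adjusted over the list alone; median -0.21, adjusted p = 7.79e-10, or 0.264 with an estimated correlation), with the complement genes C1qa (-0.31 ± 0.04) and C1qb (-0.29 ± 0.04) and with Selplg (-0.35 ± 0.04). Fibroblast and meningeal markers fell: 13 of 17 were lower and 0 higher (14 and 0 adjusted over the list alone; median -0.27, adjusted p = 7.57e-09, or 0.264 with an estimated correlation), with the matrix genes Dcn (-0.51 ± 0.06) and Col1a1 (-0.32 ± 0.04). Endothelial and mural markers had a median of -0.15 (8 fell of 24, 9 adjusted over the list alone), oligodendrocyte precursor markers -0.15 (4 fell of 13, 5 adjusted over the list alone), astrocyte markers -0.11 (7 fell and 3 rose of 25, 10 and 4 adjusted over the list alone) and myelin markers -0.08 (9 fell and 1 rose of 25, the same adjusted over the list alone). Their adjusted p were 0.00176, 0.0160, 0.00951 and 0.00422, or 0.454, 0.335, 0.518 and 0.485 with an estimated correlation. Interneuron markers (median -0.13, 8 fell and 2 rose of 20, 13 and 2 adjusted over the list alone, adjusted p = 0.00259, or 0.264 with an estimated correlation) included the serotonin receptor gene Htr3a at -0.47 ± 0.05. CA3 pyramidal markers had a median of -0.13 (3 fell and 0 rose of 11, adjusted p = 0.00827) and striatal markers -0.13 (2 fell and 1 rose of 12, 0.0357). Dentate granule markers had a median of -0.10 (4 fell and 1 rose of 14, 0.0331) and genes near Fmr1 on chromosome X -0.09 (3 fell and 0 rose of 11, 0.0331). Adjusted over the list alone these counts were 3 and 0, 2 and 1, 6 and 1, and 3 and 0. Rgs9 of the striatal list (0.21) and Stxbp6 of the dentate list (0.14) rose. Rgs9 lost its call without KO library 1 or 3 or WT library 1, 2 or 4 (adjusted p up to 0.185), and Stxbp6 without KO library 3 (up to 0.0753). With an estimated correlation the adjusted p of these 4 lists were 0.264, 0.316, 0.485 and 0.353.

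Thalamic markers shifted up, with 5 of 12 higher and 0 lower (5 and 0 adjusted over the list alone; median 0.21, adjusted p = 0.0131, or 0.485 with an estimated correlation). Ramp3, a receptor accessory protein gene, rose by 0.37 ± 0.09. The 4 WT libraries differed widely in this list, with an SD of 0.215 against 0.0210 in the 3 KO libraries, and the call was lost without WT footprint library 3 (adjusted p = 0.0550). Calls were also lost for the striatal list without WT library 2 (0.0804) or 3 (0.0558), for the dentate list without KO library 2 (0.288) or WT library 3 (0.0696) and with the length trend removed (0.0770), and for the chromosome X list without KO library 2 (0.0699), WT library 2 (0.0577) or WT library 4 (0.0561). Ttr, a choroid plexus transcript that spills easily between samples and was named after its values were seen, was higher in KO at 1.79 ± 0.37 in footprints (adjusted p = 0.00758) and 1.46 ± 0.20 in RNA (adjusted p = 0.0210). Other members of the choroid plexus and ependyma list were mixed in footprints. Kl was at -0.22 (adjusted p = 0.0415) and Rarres2 at -0.27 (0.0551), while Ccdc153 was at 0.56 (0.0774). In RNA Kl was at -0.21 (0.130) and Sostdc1 at -0.68 (0.255). The choroid plexus list did not pass in footprints (median 0.06, 1 rose and 1 fell of 10, adjusted p = 0.900) or in RNA (median -0.13, mean 0.0086, test down, 1 rose and 0 fell of 6, adjusted p = 0.601). The beta-globin gene Hbb-bs, also named after the fact, was lower at -1.12 ± 0.16 and -1.47 ± 0.19.

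**Figure D2:**
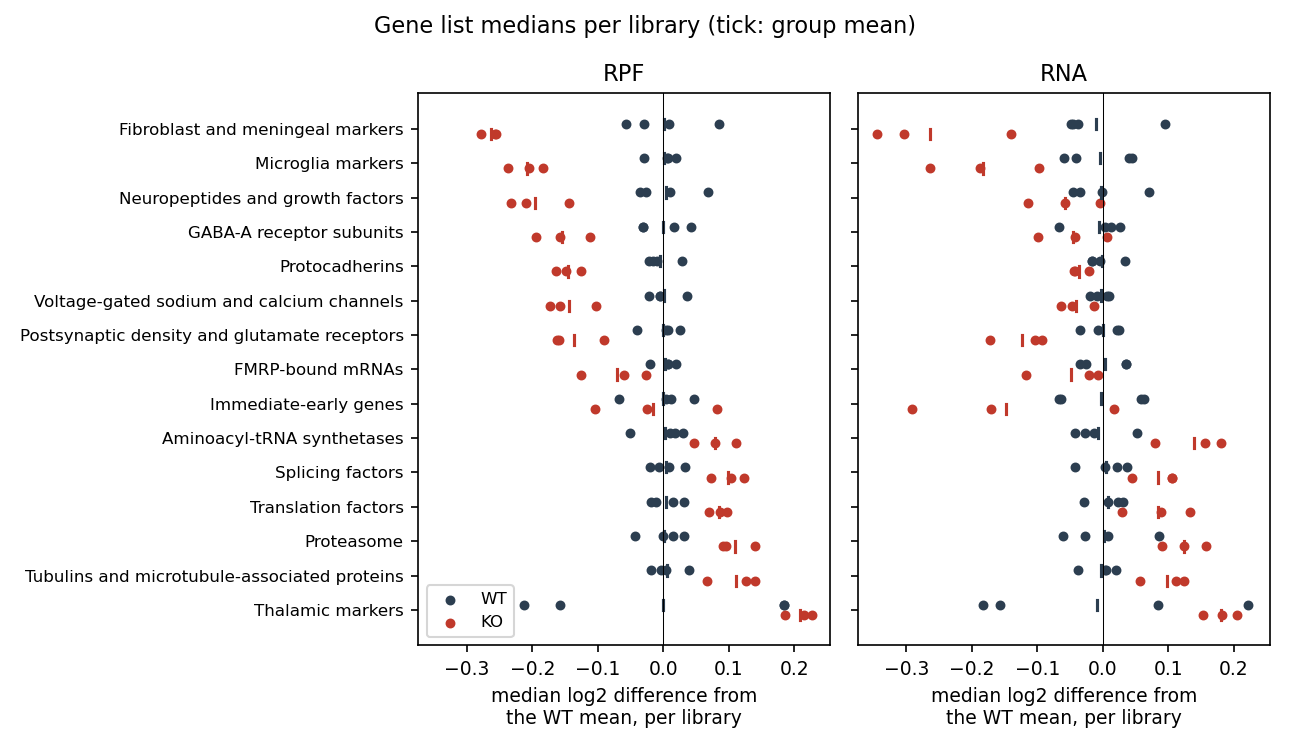
Median log2 difference from the WT mean (horizontal axes) of 15 gene lists in each WT and KO library, for footprints (left) and RNA (right), with the group mean as a tick. In footprints the 3 KO libraries lie below all 4 WT libraries for the microglia, fibroblast and protocadherin lists, and the WT libraries scatter widely for the thalamic list.

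In RNA, Cdc26, a subunit of the anaphase-promoting complex, rose from 17.4 ± 2.63 to 36.4 ± 8.06 TPM, a log2 fold change of 1.08 ± 0.17 (adjusted p = 0.00505). Prkcd rose by 0.94 ± 0.15 (adjusted p = 0.00672, or 0.0714 with the apparent removed direction of the libraries as a covariate) and Fundc2, a mitochondrial outer membrane protein gene, by 0.67 ± 0.12 (adjusted p = 0.00961). Gabra2 fell from 181 ± 6.46 to 119 ± 7.68 TPM, a log2 fold change of -0.61 ± 0.05 (adjusted p = 4.43e-05), close to its change in footprints. Hba-a2 (-1.57 ± 0.24), Ntn5 (-0.76 ± 0.13) and the melanocortin receptor gene Mc4r (-0.73 ± 0.13) also fell. Other calls were lost without single libraries. Klf2, a transcription factor gene (-0.79 ± 0.16), Agtrap, which encodes an angiotensin receptor-associated protein (-0.86 ± 0.17), and Uqcc3, an assembly factor gene of respiratory complex III (0.80 ± 0.17), missed the threshold without KO RNA library 2, with adjusted p of 0.0521, 0.0648 and 0.0560 as the highest over their alternatives. Over the same alternatives their log2 fold changes were -1.07 to -0.64, -1.07 to -0.66 and 0.67 to 0.94. The replication helicase gene Mcm3 (0.65 ± 0.12) missed it without KO RNA library 2 or WT RNA library 1, and Cbln4, a synaptic organiser gene (-0.78 ± 0.15), without KO RNA library 3 or WT RNA library 4. Further genes missed it without any one of several RNA libraries, given with the highest adjusted p over all alternatives: Rab37 (0.88 ± 0.20) without KO 1, 2 or 3 and WT 1, 3 or 4 (0.143), Ptma (0.87 ± 0.22) without KO 2 or 3 and WT 1, 3 or 4 (0.096), Myd88 (0.64 ± 0.12) without KO 1 or 2 and WT 1 or 4 (0.0862). The same held for Brms1 (0.64 ± 0.14) without KO 2 or 3 and WT 4 (0.0909), Cyb5rl (0.64 ± 0.15) without KO 1 or 3 and WT 1 or 4 (0.178), Hrk (-1.04 ± 0.21) without KO 2 or 3 and WT 1, 3 or 4 (0.139). It also held for Ugt1a6a (-0.90 ± 0.15) without KO 1, 2 or 3 and WT 1, 2, 3 or 4 (0.14), Dlk1 (-0.76 ± 0.19) without KO 1, 2 or 3 and WT 1 or 4 (0.199), Bhlha9 (-0.74 ± 0.16) without KO 1 or 2 and WT 1, 2 or 4 (0.162). Ptma and Ugt1a6a share reads with pseudogenes or overlapping transcripts. Ugt1a6a RNA also lay near the floor of the values, at 1.26 TPM in KO and 2.36 TPM in WT. Mcm3 RNA was low as well, at 3.81 TPM in KO and 2.44 TPM in WT.

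In all, edgeR called 293 genes higher and 383 lower in KO RNA of 13877 tested (4.87%), of which 16 and 28 changed by at least 1.5-fold. These counts moved strongly with single libraries. The higher and lower genes numbered 162 and 157 without KO RNA library 1, 109 and 138 without KO library 2, 150 and 171 without WT library 1, 175 and 236 without WT library 2, and 94 and 144 without WT library 4. Without WT library 3 the higher genes numbered 183. With the apparent removed direction of the libraries as a covariate (libraries 1 and 2 against 3 and 4) they were 150 and 210, and with the replicate number as a block 73 and 125.

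Of the 40 lists, 19 shifted in RNA, 8 up and 11 down, and none passed with an estimated correlation. Proteasome genes shifted up (median 0.12, 5 rose and 0 fell of 37, 11 and 0 adjusted over the list alone, adjusted p = 5.71e-07, or 0.337 with an estimated correlation), as did aminoacyl-tRNA synthetases (median 0.15, 6 rose and 0 fell of 23, 11 and 0 adjusted over the list alone, adjusted p = 1.43e-05, or 0.337 with an estimated correlation). Psmc3 rose by 0.26 ± 0.05, a call lost without KO RNA library 2 (adjusted p up to 0.0562), and the alanyl and tyrosyl synthetase genes Aars and Yars rose by 0.38 ± 0.06 and 0.34 ± 0.06. Splicing factors (median 0.07, 10 rose and 1 fell of 89, 21 and 2 adjusted over the list alone), translation factors (0.08, 6 and 0 of 66, the same adjusted over the list alone), nuclear-encoded respiratory chain genes (0.08, 6 and 0 of 82, 7 and 0 adjusted over the list alone) and tubulins with microtubule-associated proteins (0.10, 3 and 0 of 32, 8 and 0 adjusted over the list alone) followed, with adjusted p of 8.11e-05, 9.03e-05, 1.36e-04 and 5.40e-04. With an estimated correlation these were 0.319, 0.333, 0.597 and 0.315. Postsynaptic genes shifted down (median -0.12, 12 fell and 1 rose of 60, 20 and 2 adjusted over the list alone, adjusted p = 6.96e-07, or 0.315 with an estimated correlation), with the scaffold genes Shank1 at -0.42 ± 0.08 and Dlgap3 at -0.31 ± 0.06. Shank1 lost its call without KO RNA library 2 (adjusted p up to 0.0521), and Dlgap3 without KO RNA library 1 or 2 (up to 0.0568). The respiratory chain list did not pass without KO RNA library 2 (median 0.04, adjusted p = 0.0811).

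Markers of microglia (median -0.21, 9 fell of 22, adjusted p = 4.11e-06), fibroblasts and meninges (-0.19, 5 of 17, 8.94e-06) and oligodendrocyte precursors (-0.17, 4 of 13, 1.94e-04) shifted down in RNA too, with 9, 7 and 5 members lower when adjusted over the list alone. With an estimated correlation their adjusted p were 0.315, 0.319 and 0.319. Cx3cr1 of microglia fell by 0.33 ± 0.06, Fn1 of the matrix by 0.45 ± 0.07 and Olig2 of the oligodendrocyte lineage by 0.52 ± 0.08. Thalamic markers shifted up (median 0.18, 3 rose of 12, 6 adjusted over the list alone, adjusted p = 3.80e-04, or 0.512 with an estimated correlation). The WT libraries of this list scattered widely (SD 0.195 against 0.0258 in KO) and the highest of them, at 0.221, lay above every KO library (highest 0.205). CA1 markers (-0.15, 1 fell and 0 rose of 11, adjusted p = 8.51e-04), which include Wfs1 at -0.52 ± 0.06, and CA3 markers (-0.15, 2 fell and 0 rose of 11, 0.0121) shifted down (3 and 2 fell adjusted over the list alone), with adjusted p of 0.369 and 0.315 with an estimated correlation. Immediate-early genes, which report recent neuronal activity, had a median of -0.14 (3 fell and 27 did not pass, 3 fell adjusted over the list alone, adjusted p = 1.87e-04, or 0.597 with an estimated correlation), with Egr1 at -0.43 ± 0.09 and Dusp1 at -0.33 ± 0.07. The list call was lost without KO RNA library 2 (adjusted p = 0.105), as was that of Egr1 (up to 0.0602), and Dusp1 lost its call without KO RNA library 2 or WT RNA library 1 or 4 (up to 0.074). The FMRP-bound list had a median of -0.04 (11 fell and 7 rose, 19 and 8 adjusted over the list alone, adjusted p = 0.0250, or 0.687 with an estimated correlation), a call lost without KO RNA library 2 (0.580), WT library 1 (0.201) or WT library 4 (0.158) with the length trend removed (0.641) and with a replicate block (0.132). Potassium channels (median -0.07, 2 fell of 73, adjusted p = 0.0121), sodium and calcium channels (-0.03, 3 fell of 29, 0.0250), GABA-A subunits (-0.05, 2 fell of 13, 0.0270) and mitochondrial ribosomal proteins (0.02, 1 rose of 77, 0.0449) passed by less. Adjusted over the list alone 0, 5 and 2 fell and 0 rose in these 4 lists. With an estimated correlation their adjusted p were 0.426, 0.315, 0.571 and 0.687. Of these, the potassium channel call was lost without KO RNA library 2 (0.0782), the GABA-A call without KO library 3 (median 0.0068, adjusted p = 0.231), WT library 2 (0.0569) or WT library 4 (0.0501), and the mitochondrial call without KO library 2 (0.564) or WT library 1 (0.112), 2 (0.0532) or 4 (0.158). With the length trend removed the sodium and calcium channels (0.119) and the mitochondrial list (0.0837) did not pass, nor did the mitochondrial list with a replicate block (0.175).

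Genes called in footprints mostly changed in the same direction in RNA, although most of them were not called there. Of 13875 genes tested in both assays, 158 were called higher in both (24.6 expected for independent assays) and 195 lower in both (41.3 expected for independent assays). Both assays come from the same lysates, so they are not independent, and differences between the pools enter both. Opposite calls numbered 3 for genes higher in footprints and 1 for genes lower in them. No RNA call was made for 1005 of 1166 genes higher and 1301 of 1497 genes lower in footprints. Genes called higher in footprints had a median log2 fold change of 0.18 in footprints and 0.12 in RNA, and 82.8% had the same sign in RNA. Genes called lower had medians of -0.21 and -0.12, and 86.4% had the same sign. Across genes, which are not independent replicates, the log2 fold changes of the assays had a Pearson correlation of 0.43 and a Spearman correlation of 0.42. Serpina3n (RNA -0.68 ± 0.06), Klk8 (RNA -0.73 ± 0.09) and Lmna (RNA 0.36 ± 0.10) passed in both assays (adjusted p in RNA 5.55e-05, 0.00132 and 0.0497), whereas Hes5, Arpc1b and Lcor had RNA values of -0.01, 0.03 and -0.07 that did not pass. Of the genes called in RNA, 357 were also called in footprints and 319 were not. Among large RNA changes, Uqcc3 (0.01), Fundc2 (-0.03), Mcm3 (0.0003), Klf2 (0.002) and Hrk (-0.09) did not pass in footprints. Ptma, higher in RNA, was lower in footprints (-0.21 ± 0.06, adjusted p = 0.0238). Prkcd, Hba-a2, Ntn5, Cbln4 and Dlk1 passed in footprints in their RNA direction.

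**Figure D3:**
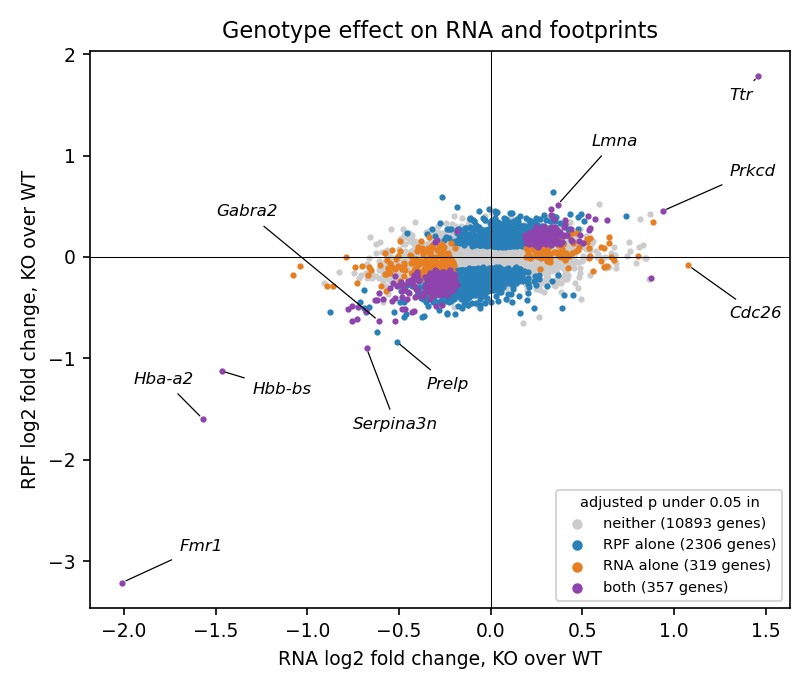
Log2 fold change, KO over WT, in RNA (horizontal axis) and footprints (vertical axis) for 13875 genes, coloured by the assays in which the adjusted p is under 0.05. Fmr1 lies at -2.01 and -3.21, and 357 genes pass in both assays.

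A change of footprints relative to RNA (translational efficiency, TE) was called for few genes. Apart from Fmr1, Cdc26 had a lower TE (-1.16 ± 0.18, adjusted p = 0.0101): its RNA rose while its footprints were at 41.1 ± 2.28 TPM in KO and 43.0 ± 2.20 TPM in WT. Pcbp2, which encodes a poly(rC)-binding regulator of mRNA stability and translation, had a higher TE (0.44 ± 0.06, adjusted p = 0.00108), with footprints up from 299.7 ± 5.45 to 361 ± 9.03 TPM (log2 fold change 0.26 ± 0.04) and RNA down from 370.0 ± 10.8 to 326 ± 1.43 TPM (-0.18 ± 0.05). Dact3, a Wnt pathway antagonist gene, also had a higher TE (0.53 ± 0.09, adjusted p = 0.0110), with RNA lower by -0.38 ± 0.06 and footprints at 0.16 ± 0.06. In all, 2 genes were higher and 2 lower of 13875 tested, against 777 and 779 at an unadjusted p under 0.05. The counts depended on the test and on single libraries. DESeq2 called 52 and 39. Leaving out KO RNA library 3 gave 88 and 27 with edgeR. The call for Cdc26 was lost without KO RNA library 2 (adjusted p = 0.0967), and that for Dact3 without KO footprint library 2 or WT footprint library 3 (adjusted p up to 0.0909). Without KO footprint library 2 or WT footprint library 3 only 1 gene was higher, without WT RNA library 3 the counts were 8 and 4, and without WT footprint library 2 the higher genes numbered 11.

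Protocadherins had fewer footprints per RNA in KO (median -0.09, 0 of 72 members passing alone, 1 lower adjusted over the list alone, adjusted p = 6.79e-05, or 0.645 with an estimated correlation). Immediate-early genes had more (median 0.16, 0 of 30 passing alone, 2 higher adjusted over the list alone, adjusted p = 7.16e-04, or 0.968 with an estimated correlation). This call was lost without KO RNA library 2 (adjusted p = 0.160). Neuropeptides and growth factors had fewer (median -0.08, 4 of 27 lower adjusted over the list alone and 0 over all genes, adjusted p = 0.0344, or 0.968 with an estimated correlation), a call lost without KO RNA library 3 (0.176), WT RNA library 3 (0.0943) or 4 (0.0572), KO footprint library 1 (0.0923) or WT footprint library 2 (0.116). The FMRP-bound list had a median TE change of -0.03 (adjusted p = 0.192). The number of lists that passed rose from 3 to 8 without KO RNA library 2, to 5 without WT RNA library 1, to 6 without KO footprint library 1 and to 7 without KO footprint library 2.

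Within WT slices, gene groups differed widely in footprints per RNA. The median log2 ratio of footprint to RNA CPM was -0.10 over 13295 genes with an SD of 1.06. Neuropeptides and growth factors had a median of 1.67 (SD over the 4 WT footprint libraries 0.0394, adjusted p = 9.26e-07), GABA-A subunits 0.89 (SD 0.0690, 0.0259) and protocadherins 0.44 (SD 0.0417, 3.73e-05), and splicing factors lay at 1.2 (SD 0.0142, 9.56e-13). Cytosolic ribosomal proteins lay at -1.45 (SD 0.0415, adjusted p = 1.14e-12), potassium channels at -0.86 (SD 0.0192, 7.31e-05) and FMRP-bound mRNAs at -0.71 (SD 0.0170, 6.46e-07). Of 39 lists 19 shifted, 14 up and 5 down, and with an estimated correlation none passed (adjusted p from 0.279 to 0.663 for these 7 lists). Library preparation differs between the assays and enters this ratio.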

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

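The test of gene length for the membrane and cytosolic lists, and the choice of the 10 lists it uses, were made only after the result was seen.

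A test of the difference between the assays set apart 4 genes and 3 lists whose KO change differs between footprints and RNA: Dact3 (0.53), Pcbp2 (0.44), Cdc26 (-1.16), Fmr1 (-1.20), protocadherins (-0.094), immediate-early genes (0.16) and neuropeptides with growth factors (-0.077). With an estimated correlation the lists did not pass (adjusted p = 0.645, 0.968 and 0.968), and with fry 0 lists passed in TE. A single library lay far from the other 3 of its group in 6 of 129 groups, where chance gives 6.45. Its gap to the nearest library, as a share of the group's range, was 0.965 for autism-linked genes (WT RPF library 3), 0.896 for interneuron markers (WT RPF library 4), 0.909 for striatal markers (WT RPF library 2), 0.881 for oligodendrocyte precursor markers (WT RNA library 3), 0.922 for fibroblast and meningeal markers (WT RNA library 1) and 0.830 for CA3 markers (WT RNA library 4).

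Of the 35 splits of the 7 libraries into 3 and 4, only the real one (1 of 35) called as many genes in each comparison: 2668 in RPF against at most 0 in any other split, 676 in RNA against at most 1, and 4 in TE against at most 0. The splits are not exchangeable if an adjustment kept genotype and removed another direction, since the other splits are then disadvantaged, so these counts do not exclude chance by themselves. With the apparent removed direction as a covariate 1953 genes were called in RPF, so allowing for that direction alone left most of the RPF calls. The covariate cannot restore the spread of low counts, and a replicate block left 421 higher and 872 lower genes. A lowered spread therefore stays a candidate explanation for part of the RPF calls. In RNA the same covariate left 150 higher and 210 lower genes of 293 and 383, so a lowered spread stays a candidate explanation for part of the RNA calls.

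The FMRP-bound list was lower in footprints (median -0.08). Removing each library's length trend brought its median to -0.012, and the list was also lower in RNA, at -0.039. Gene length and a change of the RNA level are therefore both candidate explanations for its shift. An effect of FMRP on translation of these mRNAs stays open and is not separated from them here.

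Channel, receptor and adhesion lists (252 genes, RPF median -0.12) were lower and 5 cytosolic lists (247 genes, 0.10) higher in KO. This difference of 0.22 is between lists picked for their shifts. Cytosolic ribosomal proteins (0.02, camera adjusted p = 0.163), mTORC1 genes (0.06, 0.0544) and kinesins with dyneins (0.02, 0.217) did not pass and are not among them. Nor are presynaptic genes (-0.003, 0.989) and cholesterol synthesis genes (0.02, 0.428), which did not pass either. With the length trend removed mTORC1 genes (0.06, camera adjusted p = 0.0406) and kinesins with dyneins (0.05, 0.0147) did pass. The medians of the membrane and cytosolic sets were -0.07 and 0.10 in RNA and -0.05 and -0.015 in TE, so the sets differed in RNA too. Gene length as the whole source is argued against, since the RPF difference was 0.20 with the length trend removed. Housekeeping genes of the endoplasmic reticulum and lysosome were lower as well: of 87 genes 56 fell and 0 rose in RPF (median -0.17, p = 1.09e-20, or 0.126 with an estimated correlation). That list was written before it was tested, although its member Os9 had been seen among genes ranked by TE. Lower recovery of mRNAs translated at the endoplasmic reticulum in the KO lysates is thus a candidate explanation, as is a biological change of translation there. A loss of these mRNAs from the shared lysates would by itself lower RNA and footprints alike. The median of the 87 genes was -0.09 in RNA and -0.10 in TE (camera p = 1.43e-07 in TE, or 0.209 with an estimated correlation). These values do not settle between the explanations.

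Gabra2 and Nnt carry variants that differ between C57BL/6 substrains, so a different background of the KO animals may shift both, although per the labels KO and WT were littermates, which goes against separate backgrounds. Of these 2 genes, 1 passed in RNA with at least a 1.5-fold change: Gabra2 was 1.53-fold lower in RNA, while Nnt was at -0.08 (adjusted p = 0.493). In RPF Nnt was at -0.17 (adjusted p = 0.0278). The list of 7 measured substrain genes did not pass in RPF (median -0.006, 2 fell and 0 rose, camera adjusted p = 0.366). It did not pass in RNA either (median 0.02, mean -0.07, test down, 1 fell and 0 rose, 0.417). A substrain difference and an effect of Fmr1 loss on Gabra2 cannot be told apart, because the labels do not give the substrain and no table holds genotypes of the animals.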

How the results depend on the processing

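The removed direction as a covariate was chosen only after the data were seen.

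The alternatives covered the genes named by the rule and the passing members of lists that passed, each in that comparison. None of these genes changed direction. Ttr, Hbb-bs, Kl, Rarres2, Ccdc153, Sostdc1, Nnt, Hspa5 and Hsp90b1 were not run through the alternatives. The GABA-A list in RNA had a median of 0.0068 without KO RNA library 3, against -0.05 with all libraries. Without KO RNA library 1 the higher genes in RNA (162) outnumbered the lower ones (157). Higher and lower genes in RPF numbered 421 and 872 with a replicate block, and 671 and 989 with the block and length trend together. In RNA they numbered 168 and 244 with limma on TPM, 540 and 655 in a fit over all libraries, 73 and 125 with the block, 71 and 103 with block and length, and 150 and 210 with the removed direction. In TE they numbered 52 and 39 with DESeq2, 39 and 31 with limma, 47 and 22 with voom and 12 and 8 with the length trend, and 5 were higher with block and length. The block was not part of the test written beforehand, and the labels state no pairing of the genotypes by number. Correlations of same-number KO and WT libraries (-0.35 to -0.06 in RNA and -0.45 to 0.02 in RPF) do not settle such a pairing, since the apparent removal of a direction by itself makes them low. Between RNA and RPF the same-number correlations were -0.05 to 0.18 in KO (1 of 3 libraries best with its own number) and 0.02 to 0.11 in WT (3 of 4), which leaves open whether the numbers follow the shared lysates.

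With an estimated correlation 0 lists passed in RPF, 0 in RNA, 0 in TE and 0 in WT (5, 5 and 2 at an unadjusted p under 0.05 in RPF, RNA and TE). With fry 21 passed in RPF, 11 in RNA, 0 in TE and 35 in WT.

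Leaving out single libraries gave 717 to 1090 higher and 1051 to 1294 lower genes in RPF, 94 to 353 and 138 to 521 in RNA, and 1 to 88 and 2 to 27 in TE. Passing lists ranged from 22 to 28 in RPF, 16 to 23 in RNA, 2 to 8 in TE and 17 to 20 in WT. The Fmr1 change ranged from -3.25 to -3.18 in RPF and -2.12 to -1.91 in RNA. DESeq2 gave no adjusted p for Fmr1 in RNA. Of 108 named results in RPF 18 lost their call without at least 1 library, of 74 in RNA 43, and of 4 in TE 2. The block ended 15 calls in RPF and 34 in RNA, and the removed direction 5 and 17.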

Other observations

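The secretory housekeeping genes were not part of the lists written first. In RNA their median was -0.09, with 67 of 87 lower and 1 passing, and in TE it was -0.10, with 72 of 87 lower and 0 passing in edgeR. In footprints 86 of the 87 were lower and all 3 KO libraries lay below every WT library. The chaperone genes Hspa5 and Hsp90b1 of the endoplasmic reticulum fell by 0.41 and 0.31 in footprints.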
